A study of Homo sapiens with 3 samples.

How the data were processed

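Single-cell RNA sequencing (10x Genomics 3' v3.1 chemistry) was measured in 3 spinal organoid slices, named A, B and C, each from a separate organoid. The organoids were grown from 1 cell line, the human embryonic stem cell line H9, in batch 1, were sliced at day 25 and were dissociated with papain at day 100. The 3 slices form 1 group with no untreated or control arm, so every comparison was made between cell classes inside the slices. The slice is the replicate (n = 3), and all 3 share the cell line and the batch.

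The deposited files hold raw UMI counts (unique molecular identifiers, 1 per captured RNA molecule) for every droplet barcode of each slice, empty droplets included. Per the file headers the counts were made with Cell Ranger 4, and per the labels the genome build was GRCh38. No normalization had been applied to the deposited counts, which were whole numbers. Each file held 36601 genes. Gene coordinates come from GENCODE release 29 on GRCh38, which may differ from the annotation the authors used, and all 236 named gene identifiers had a position there.

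Total UMIs were 122534120 in slice A, 130900552 in slice B and 112151999 in slice C. Cells were called as barcodes with at least 10% of the 99th percentile UMI count of the 10000 highest barcodes of the slice. That minimum was 2637 UMIs in slice A, 3125 in slice B and 2581 in slice C, and 11726, 12129 and 12500 barcodes passed it. Cells with fewer than 500 genes or more than 10% mitochondrial UMIs were removed, which left 10678, 11267 and 11508. The cells with the highest Scrublet doublet scores were then removed, 0.8% for each 1000 cells, which took out 912, 1016 and 1059 cells. Confidence intervals of cell shares are exact 95% Clopper-Pearson intervals and cover counting error only. A share of 0 allows up to 3 cells of the total.

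Clustering and testing used different genes. Counts were scaled to 10000 UMIs per cell, log-transformed, and 2000 variable genes were taken from genes with an even Ensembl number and from the cell type markers, of which 136 were among them. Cells were clustered on 30 principal components and 15 exact nearest neighbours with the Leiden method at resolution 1 and seed 0, without batch correction. Genes with an odd Ensembl number that were not among the 182 markers, and gene lists fixed beforehand, were kept out of the clustering and were the only ones tested, 18436 genes in all. Of 492 listed genes 491 were found. PRRXL1 was absent, and MATR3 was left out because it had more than 1 identifier. Genes kept out of the clustering still vary together with genes used in it, so adjusted p values between classes are not free of the clustering.

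A cluster was named after a cell type when at least 3 of its markers were raised, meaning 20 CPM (UMIs of the gene scaled to a common total) or more and a log2 ratio of at least 1 against the other cells with 10 CPM added to both. The type with the highest mean ratio gave the name, unless the 10 leading genes of the cluster held more markers of another type. The clustering gave 27 clusters, of which 7 stayed unnamed under these rules. Neuron-like cells were clustered again into 16 sub-clusters for the motor, excitatory and inhibitory classes. Some sub-clusters were set aside by a rule made after the clusters were seen, and the results, comparison and alternative that need them are not reported here. Names with "like" rest on RNA alone.

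Counts were summed per slice and class for classes with at least 50 cells in every slice. Genes were tested with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood F test) with the slice as a block, and p values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. Fold changes are log2 values with a standard error (SE) taken as the log2 fold change divided by the square root of F. Gene lists with at least 5 tested genes were compared with the other tested genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. No list passed with an estimated correlation, and its adjusted p is given beside each call. Shares of neurons with a UMI of a gene were counted after thinning every cell to 2000 UMIs, beside the share in astroglia-like cells as background.

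The slice was a block because both sums of a comparison come from 1 slice. The deviations of the sums of a slice from their class means correlated across genes at 0.22, 0.35 and 0.42 in slices A, B and C for neuron-like and astroglia-like cells. They correlated at 0.46, 0.49 and 0.41 for oligodendrocyte lineage-like and astroglia-like cells, and at 0.09, 0.14 and 0.18 for inhibitory and excitatory neuron-like cells. These are correlations across genes, and genes are not independent replicates. Without the block the numbers of genes called were 5710, 5213 and 209, against 5763, 5496 and 290 with it.

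The fits were tested on simulated data made from the same sums. Of genes changed 4-fold, 100% were recovered in each reported comparison, and of genes changed 2-fold 73% to 92%. False calls were 2.81% to 7.11% of all calls, and 0 of 30 unchanged gene lists were called. The simulation drew each gene independently, without differences between slices, and changed 200 genes in each comparison. It therefore does not give the rate of false calls for lists of correlated genes. Nor does it give that rate for comparisons in which many more genes differ.

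The planned comparisons, gene lists, cell type markers, most other settings and the rule for named genes were fixed before the data were examined. Cluster 3 against astroglia-like cells, the rule that set sub-clusters aside, the subtraction of free RNA from barcodes of 200 to 450 UMIs and the regional values without unnamed clusters came after. Named genes are up to 3 genes with the largest change in each list that passed and in a set of lists named in every case, the 8 highest and 8 lowest genes with 20 CPM or more, the HOX genes at 10 CPM or more over all cells, and transmitter or domain genes in 1% or more of thinned neurons. Motor neuron-like against other neuron-like cells was planned and was not run, since the slices held 13, 14 and 25 motor neuron-like cells. Alternatives covered normalization, the test, the filter, the block, each slice left out, subtraction of free RNA, clustering, the UMI minimum, the mitochondrial limit, doublets and thinning. Other software was R 4.3.3, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and scikit-learn 1.9.0.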

Results

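RNA was counted cell by cell in 3 slices of human spinal cord organoids, grown from H9 embryonic stem cells with a WNT agonist (CHIR99021), FGF-2, a hedgehog agonist (SAG) and retinoic acid. These factors direct stem cells toward ventral spinal cord, and the slices were then kept in medium with GDNF, BDNF and IGF-1 until day 100. The question the data address is which spinal cell types such slices hold. After filtering, 9766 cells of slice A, 10251 of slice B and 10449 of slice C remained, 30466 in all. The median cell had 6733 UMIs in slice A, 5924 in slice B and 4700 in slice C, and 2908, 2662 and 2308 genes. The median mitochondrial share was 5.09%, 5.40% and 5.78%.

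Glia made up most of the named cells. Astroglia-like cells, the support cells marked by GFAP and AQP4, were 32.6% ± 3.12 (SD, n = 3) of all cells. Oligodendrocyte lineage-like cells, which make myelin or are precursors of the cells that do, were 14.4% ± 0.920 (SD, n = 3), and ciliated ependymal-like cells, which line the central canal, were 13.3% ± 2.47 (SD, n = 3). Neuron-like cells were 9.83% ± 2.74 (SD, n = 3), a share of 7.02% in slice A (95% Clopper-Pearson interval 6.53% to 7.55%), 12.5% in slice B (11.9% to 13.2%) and 9.97% in slice C (9.40% to 10.6%). Cycling-like cells were 5.14% ± 0.771, floor plate-like cells, the ventral midline of the spinal cord, 3.64% ± 1.37, and neural progenitor-like cells 3.59% ± 1.01 (SD, n = 3 each). Neural crest or Schwann-like cells were 0.125% ± 0.157 (SD, n = 3), and 32 of the 39 came from slice C; the share was 0.558% with genes centred by slice, where slice B had the most (1.29%). Mesenchymal or fibroblast-like cells numbered 98 in slice C, 2 in slice B and 0 of 9766 in slice A, which allows a share of up to 0.0307%. The remaining 17.1% ± 2.08 (SD, n = 3) lay in clusters that no marker list named. The largest of them, called cluster 3 here, held 2629 cells led by ANGPTL4, ADM and SLC2A1, genes known to respond to low oxygen, with a median mitochondrial share of 1.72%. The share of astroglia-like cells was 23.0% at a finer clustering, where that of the oligodendrocyte lineage was 21.8%, and ependymal-like cells were 3.99% with a mitochondrial limit of 5%. With that limit floor plate-like cells were 8.08% and neural progenitor-like cells 1.78%. No cluster was named floor plate-like with a minimum of 1000 UMIs or at a coarser clustering, and neural progenitor-like cells were 6.01% with variable genes of odd and even Ensembl number.

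**Figure D1:**
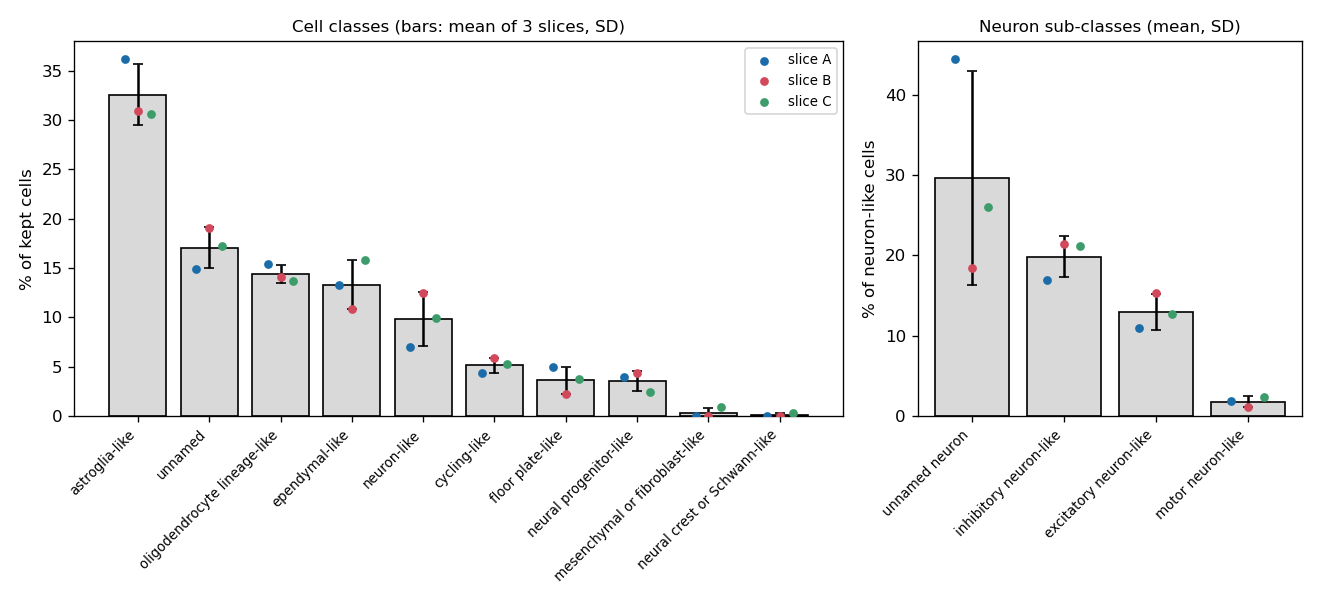
Share of each cell class in percent of kept cells (left) and of each neuron class in percent of neuron-like cells (right); bars are means of 3 slices, error bars the SD, and points the slices A, B and C. Astroglia-like cells are the largest class at 32.6% and inhibitory cells are 19.9% of neuron-like cells.

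HOX genes, which encode position along the body axis, were expressed as far as group 9 and not beyond. HOXB8 (ENSG00000120068, GRCh38 chromosome 17, 48611377 to 48614939) was the highest at 136 CPM ± 21.5 (SD, n = 3) over all cells, followed by HOXB7 (ENSG00000260027, chromosome 17, 48607227 to 48633572) at 120 ± 11.3 and HOXA5 (ENSG00000106004, chromosome 7, 27141052 to 27143668) at 106 ± 11.1. Of 39 HOX genes, 16 reached 10 CPM. The others were HOXB5 at 90.9, HOXB6 at 84.8, HOXA7 at 56.6, HOXB4 at 49.0, HOXA6 at 45.1, HOXB3 at 44.0, HOXB9 at 42.9, HOXB2 at 39.3, HOXD8 at 29.3, HOXA3 at 28.6, HOXA4 at 27.9, HOXC4 at 24.6 and HOXA2 at 15.04 CPM. Thoracic HOXC genes were low and uneven between slices, HOXC8 at 1.39 CPM ± 1.16 and HOXC9 at 1.88 ± 1.84 (SD, n = 3 each). HOXC8 was 0.685, 2.73 and 0.753 CPM in slices A, B and C, and HOXC9 0.430, 3.95 and 1.27 CPM. Of 12 genes of groups 10 to 13, which mark lumbar and sacral levels, 0 reached 1 CPM, and the highest was HOXA10 at 0.170 CPM ± 0.0367 (SD, n = 3). Of 13 forebrain and midbrain transcription factors 0 reached 10 CPM and the highest was EN2 at 1.00 CPM ± 0.109 (SD, n = 3). Cell classes differed: HOXA5 was 627 CPM ± 78.3 in excitatory neuron-like cells, 558 ± 159 in inhibitory neuron-like cells and 69.6 ± 4.99 in astroglia-like cells (SD, n = 3), and HOXC4 reached 256 ± 8.05 in excitatory neuron-like cells.

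**Figure D2:**
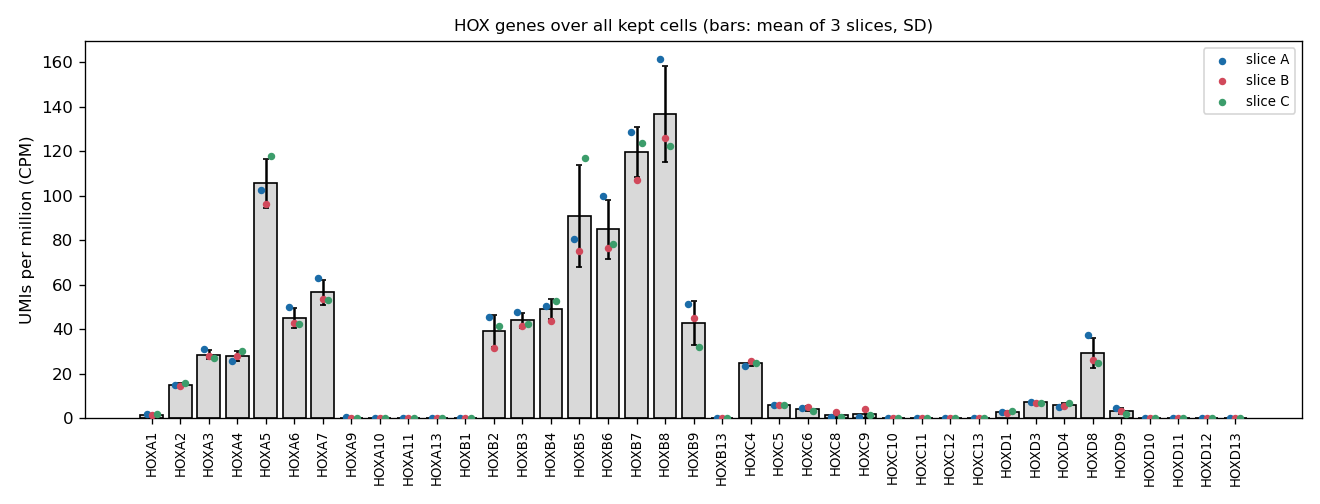
Mean CPM of each of 39 HOX genes over all kept cells; bars are means of 3 slices, error bars the SD, and points the slices A, B and C. Signal runs from group 2 to group 9 with the maximum at HOXB8 (136 CPM), and the genes of groups 10 to 13 lie under 1 CPM.

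Neurons were sorted by transmitter and domain genes. Inhibitory neuron-like cells were 19.9% ± 2.55 of neuron-like cells, excitatory neuron-like cells 13.0% ± 2.19 and motor neuron-like cells 1.80% ± 0.659 (SD, n = 3 each), and 29.7% ± 13.4 had no sub-class; these classes do not add up to all neuron-like cells. The inhibitory share was 7.82% and the excitatory share 6.05% with a mitochondrial limit of 5%. SLC17A6, the vesicular glutamate transporter of spinal excitatory neurons, had a UMI in 8.30% ± 1.65 of neuron-like cells thinned to 2000 UMIs and in 0.162% ± 0.0244 of astroglia-like cells. GAD1, which makes GABA, was found in 6.19% ± 1.37 against 0.253% ± 0.0638, SLC32A1, the vesicular transporter of GABA and glycine, in 4.89% ± 1.57 against 0.0723% ± 0.0381, and SLC6A5, the glycine transporter, in 1.21% ± 0.0968 against 0.0200% ± 0.0174. Before thinning, at median depths of 8064 and 6449 UMIs, the shares were 13.5% against 0.498% for SLC17A6, 12.8% against 1.01% for GAD1, 10.3% against 0.254% for SLC32A1 and 3.95% against 0.0620% for SLC6A5. Ventral domain genes were GATA3 at 5.03% ± 1.96 against 0.0815% ± 0.0661 and SOX14 at 3.56% ± 0.787 against 0.0199% ± 0.0173, or 8.62% against 0.356% and 8.26% against 0.174% before thinning. Of 11 dorsal interneuron factors listed, PRRXL1 could not be measured and 0 of the others reached 1%. The highest was FOXD3, also known from ventral V1 interneurons, at 0.463% ± 0.363 against 0.0209% ± 0.0181 (1.57% against 0.0618% before thinning). The shares of FOXP1, 7.64% ± 0.531 against 8.94% ± 1.04, and of NR2F1, 14.9% ± 2.32 against 51.2% ± 1.71, were no higher than the background, nor were they before thinning (24.8% against 26.4%, and 34.8% against 84.5%). Cells with both SLC17A6 and GAD1 or GAD2 numbered 22 of 3010 before thinning, 5.30% of the 415 cells with SLC17A6. GAD1 or GAD2 was found in 482 of the 3010 cells (16.1% ± 3.36, SD, n = 3), so it was rarer in cells with SLC17A6. All shares of neuron-like cells in this paragraph include the sub-clusters set aside. Detection was sparse, and a cell without a UMI may still hold the RNA. Before thinning SLC17A6 was found in 83 of 612 inhibitory neuron-like cells, and GAD1 or GAD2 in 18 of 403 excitatory ones.

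Motor neuron genes were rare. ISL1, a motor neuron transcription factor, had a UMI in 1.20% ± 0.166 of thinned neuron-like cells against 0.0608% ± 0.00358 of astroglia-like cells, and MNX1 in 0.725% ± 0.333 against 0.0691% ± 0.0413. Before thinning these shares were 3.52% against 0.141% and 2.55% against 0.211%, at median depths of 8064 and 6449 UMIs. SLC18A3, the vesicular acetylcholine transporter, had a UMI in 3.27% ± 2.54 against 0.231% ± 0.0367, or 12.6% against 0.825% before thinning. CHAT, the enzyme that makes acetylcholine, had one in 0.0320% ± 0.0554 of thinned neurons and in 0 of 9898 thinned astroglia-like cells, which allows up to 0.0303%, and in 0.685% against 0.0200% before thinning. In the 52 motor neuron-like cells ISL1, a marker used to name them, reached 35.1% ± 24.4 (SD, n = 3). ESRRG, an orphan nuclear receptor, reached 44.2% ± 9.002 (SD, n = 3). The background of ESRRG was 3.26% ± 0.152. Before thinning, at median depths of 15320 and 6449 UMIs, the shares were 76.4% against 0.141% for ISL1 and 90.1% against 10.5% for ESRRG. CHAT was found in 0 of the 52 thinned cells, which allows up to 5.77%, and had 4 UMIs in them before thinning. SLC18A3 stood at 48.3 CPM ± 11.1 in them, 14.6 ± 10.7 in excitatory and 8.76 ± 3.76 in inhibitory neuron-like cells (SD, n = 3). All shares of neuron-like cells include the sub-clusters set aside. The ISL1, MNX1, SLC18A3 and CHAT shares do not come from motor neuron-like cells alone. The planned comparison of motor neuron-like with other neuron-like cells was not run, since each slice had under 50 of them (13, 14 and 25 cells).

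**Figure D3:**
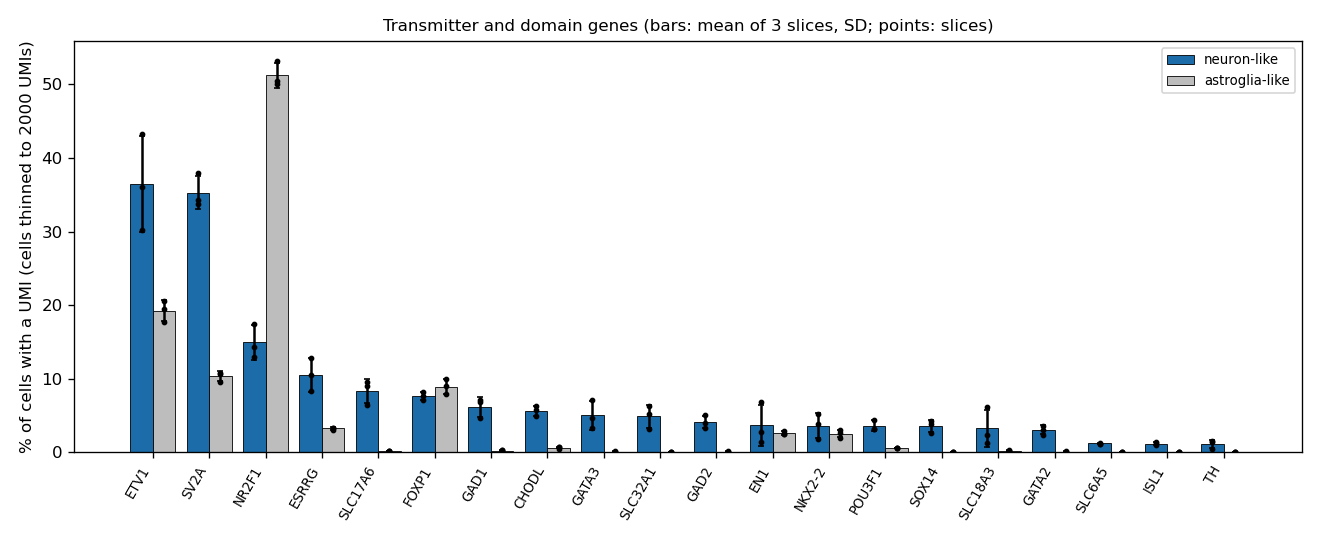
Share of cells with at least 1 UMI of a gene, in percent of cells thinned to 2000 UMIs, in neuron-like and astroglia-like cells, for the 20 transmitter and domain genes at 1% or more; bars are means of 3 slices, error bars the SD, and points the slices. SLC17A6 stands at 8.30% against 0.162%, while NR2F1 is higher in astroglia-like cells (51.2%) than in neuron-like cells (14.9%).

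Neuron-like cells differed from astroglia-like cells in the genes of axons, synapses and ion channels. The neurofilament genes NEFL (ENSG00000277586, chromosome 8, 24950955 to 24957110) and NEFM (ENSG00000104722, chromosome 8, 24913012 to 24919098) stood at 2281 CPM ± 190 and 1416 ± 84.6 in neurons, against 31.2 ± 14.3 and 16.5 ± 7.96 in astroglia (SD, n = 3). Their log2 fold changes were 6.21 (SE 0.27, adjusted p 2.67e-06) and 6.44 (SE 0.32, adjusted p 4.5e-06), higher in 3 of 3 slices. The highest genes with the same sign in all slices included FSTL5, a secreted follistatin-like protein, at 6.69 (SE 0.11, adjusted p 5.39e-07) and NXPH2, a neurexin ligand, at 6.67 (SE 0.34, adjusted p 4.63e-06). The lowest were astroglial: F3, the tissue factor gene, at -5.62 (SE 0.16, adjusted p 7.78e-07), APOE, the lipid carrier, at -5.55 (SE 0.13, adjusted p 5.51e-07) and BBOX1, of carnitine synthesis, at -5.50 (SE 0.13, adjusted p 5.51e-07). APOE stood at 37.4 CPM ± 6.60 in neurons and 1691 ± 599 in astroglia (SD, n = 3). Neuron-like cells are a mixture that includes the sub-clusters set aside, so values over the whole class depend on its makeup. Of 8587 genes tested with edgeR, 2889 were higher and 2874 lower at a Benjamini-Hochberg adjusted p under 0.05.

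All 24 genes for synaptic vesicles and release were higher in neurons, with a median log2 fold change of 3.14 (camera adjusted p 2.81e-11, and adjusted p = 0.338 with an estimated correlation); SYT4, a synaptotagmin, was at 5.84 (SE 0.22, adjusted p 1.55e-06). So were all 18 genes for neurofilaments and the axonal cytoskeleton, with a median of 2.49 (adjusted p 2.14e-09, and adjusted p = 0.338 with an estimated correlation). Of 15 voltage-gated calcium channel genes 14 were higher and 1 lower (median 2.37, adjusted p 5.60e-05, and adjusted p = 0.338 with an estimated correlation). Of 26 potassium channel genes 20 were higher and 3 lower (median 1.59, adjusted p 0.000302), and of 11 sodium channel genes 9 were higher and 2 lower (median 2.04, adjusted p 0.00318), each with adjusted p = 0.348 with an estimated correlation. SCN3B, a sodium channel beta subunit, was at 3.80 (SE 0.08, adjusted p 5.39e-07). GABA and glycine receptors had 15 of 18 genes higher and 3 lower (median 3.39, adjusted p 0.000402), and acetylcholine receptors 8 of 9 higher and 1 lower (median 3.86, adjusted p 0.00188), each with adjusted p = 0.348 with an estimated correlation. Ionotropic glutamate receptors had 11 of 17 higher and 2 lower (median 0.55, adjusted p 0.0131, and adjusted p = 0.432 with an estimated correlation), led by the NMDA receptor genes GRIN3A at 5.30 (SE 0.30, adjusted p 7.79e-06) and GRIN1 at 5.07 (SE 0.26, adjusted p 4.58e-06). Adjusted over the list alone, 12 of these were higher and 2 lower, and in the other lists of this paragraph the counts were equal to those over all genes. Glycolysis had 12 of 17 genes higher and 2 lower, and 12 and 2 adjusted over the list alone (median 0.41, adjusted p 0.00522, and adjusted p = 0.450 with an estimated correlation). ENO2, the neuronal enolase, was at 2.16 (SE 0.10, adjusted p 3.24e-06).

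Progenitor and glial pathways were lower in neurons. Of 11 Notch pathway genes, which keep progenitors and glia undifferentiated, 9 were lower and 1 higher, and likewise adjusted over the list alone (median -2.97, adjusted p 0.00118); LFNG was at -4.55 (SE 0.18, adjusted p 1.68e-06). Reactive astrocyte genes had 12 of 13 lower (median -2.69, also with the 0-count gene CXCL10 at its bound, adjusted p 8.67e-05), the hedgehog pathway, which patterns the ventral cord, 8 of 10 lower and 2 higher (median -1.64, adjusted p 0.0304), and the immediate early genes 13 of 18 lower and 4 higher (median -1.97, adjusted p 0.00687), with equal counts adjusted over the list alone. Each of these 4 lists had adjusted p = 0.348 with an estimated correlation. Cholesterol synthesis had 14 of 22 genes lower and 0 higher, over all genes and adjusted over the list alone (median -0.76, adjusted p 0.00166, and adjusted p = 0.616 with an estimated correlation); HMGCS1 was at -1.82 (SE 0.21, adjusted p 0.000238).

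The other lists did not pass camera in this comparison. HOX genes had 13 of 24 higher and 6 lower (median 0.86, adjusted p 0.126), ventral interneuron factors 5 of 8 higher and 1 lower (median 2.77, adjusted p 0.164), and motor column factors 5 of 8 higher and 1 lower (median 1.80, adjusted p 0.132). The median was -0.13 for the hypoxia response (8 of 18 higher, 5 lower, adjusted p 0.887), -0.12 for the unfolded protein and amino acid stress response (6 of 18 higher, 8 lower, adjusted p 0.582) and -0.15 for complex I of the respiratory chain (4 of 37 higher, 17 lower, adjusted p 0.0612). It was 0.86 for receptors and binding proteins of the medium's growth factors (7 of 12 higher, 2 lower, adjusted p 0.0999), 1.14 for the retinoic acid pathway (9 of 15 higher, 4 lower, adjusted p 0.0999), -0.56 for the WNT pathway (3 of 16 higher, 9 lower, adjusted p 0.0655), -0.26 for the FGF pathway (4 of 12 higher, 5 lower, adjusted p 0.472) and 0.00 for amyotrophic lateral sclerosis genes (6 of 20 higher, 6 lower, adjusted p 0.921). Adjusted over the list alone, the ventral list had 2 lower, the FGF list 6 lower and the sclerosis list 5 higher, and the other counts of this paragraph were equal. The domain genes SOX14, GATA2 and GATA3 were at 5.85, 5.53 and 5.12 (adjusted p 4.69e-06, 7.16e-06 and 9.53e-06).

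Inhibitory and excitatory neuron-like cells carried different ventral domain genes. GATA3 (ENSG00000107485, chromosome 10, 8045378 to 8075203), a transcription factor of inhibitory V2b interneurons, had 439 UMIs in inhibitory and 0 in excitatory cells, at least 98.0-fold higher against a floor of 3 counts over the class. GATA2 had 203 UMIs against 0, at least 45.3-fold higher. NKX2-2, a ventral progenitor and V3 gene, was at 3.04 (SE 0.35, adjusted p 4.55e-07), and the neurexin ligand NXPH2 at 6.25 (SE 0.26, adjusted p 2.21e-16). On the excitatory side CHODL, a membrane protein of fast motor neurons, was at -4.17 (SE 0.18, adjusted p 5.33e-16), NRN1, the neurite growth factor neuritin, at -2.89 (SE 0.11, adjusted p 6.01e-17), and SOX14, a transcription factor of ventral interneurons, at -2.88 (SE 0.16, adjusted p 9.22e-14). SOX14 stood at 128 CPM ± 33.7 in excitatory and 16.9 ± 6.31 in inhibitory cells (SD, n = 3). Of 5560 genes tested with edgeR, 146 were higher and 144 lower in the inhibitory class at a Benjamini-Hochberg adjusted p under 0.05.

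Of 8 ventral interneuron factors 6 were higher in inhibitory cells and 1 lower, over all genes and adjusted over the list alone. The list passed camera with a median of 3.01 (adjusted p 1.67e-07, and adjusted p = 0.639 with an estimated correlation), and the median was also 3.01 with GATA3 and GATA2 at their bounds. FOXP1, a motor column factor, was higher in inhibitory cells at 2.40 (SE 0.15, adjusted p 1.45e-12), and HOXC4 lower at -1.05 (SE 0.10, adjusted p 5.18e-09). The retinoic acid list was higher with 2 of 7 genes, 3 adjusted over the list alone (median 0.24, adjusted p 0.0250). Of 37 complex I genes 0 passed singly, over all genes or adjusted over the list alone, and the list had a median of 0.07 (adjusted p 0.0120). Reactive astrocyte genes likewise had 0 of 6 passing, also adjusted over the list alone, and a median of 0.25 (adjusted p 0.0330). Sodium channels were lower with 1 of 7 genes, 3 adjusted over the list alone (median -0.30, adjusted p 0.0250). The retinoic acid, complex I, reactive astrocyte and sodium channel lists each had adjusted p = 0.639 with an estimated correlation. Synaptic vesicle genes had 3 of 24 higher and 5 lower, or 4 and 9 adjusted over the list alone (median -0.15, adjusted p 0.0409, and adjusted p = 0.902 with an estimated correlation). The HOX list had a median of 0.10 while camera placed it lower, without a call (2 of 21 higher, or 7 adjusted over the list alone, and 5 lower by both, adjusted p 0.951). The neurofilament genes NEFL and NEFM were at 0.63 (SE 0.06, adjusted p 2.03e-08) and 0.57 (SE 0.07, adjusted p 8.9e-07) and turned to -0.03 and -0.33 at a finer clustering. The number of genes called was 99 with the DESeq2 Wald test and 154 without slice B.

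UGT8, CLDN11 and ENPP6 were higher in oligodendrocyte lineage-like than in astroglia-like cells, in a class named by markers of that lineage. UGT8 (ENSG00000174607, chromosome 4, 114598455 to 114678224), which makes the myelin lipid galactosylceramide, stood at 808 CPM ± 80.5 against 2.90 ± 0.559 (SD, n = 3), a log2 fold change of 8.09 (SE 0.09, adjusted p 5.89e-11). CLDN11 (ENSG00000013297, chromosome 3, 170418865 to 170454733), the claudin of myelin tight junctions, was at 805 CPM ± 109 against 5.49 ± 1.10 (SD, n = 3), a change of 7.16 (SE 0.11, adjusted p 1.03e-10). ENPP6, of newly forming oligodendrocytes, was at 7.80 (SE 0.11, adjusted p 6.65e-11), and NKX2-2, which drives oligodendrocyte differentiation, at 3.46 (SE 0.08, adjusted p 8.6e-10). BBOX1, APOE and ANOS1 were lower at -5.17 (SE 0.13), -5.09 (SE 0.08) and -4.57 (SE 0.06), with adjusted p 1.21e-09, 1.03e-10 and 6.65e-11. Of 8126 genes tested with edgeR, 2676 were higher and 2820 lower at a Benjamini-Hochberg adjusted p under 0.05, and 3529 were called with a mitochondrial limit of 5%.

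Synaptic vesicle genes were higher in the oligodendrocyte lineage for 19 of 23 genes and lower for 0 (median 1.32, adjusted p 2.75e-05), and RAB3C, a vesicle GTPase, was at 2.16 (SE 0.15, adjusted p 1.27e-06). Ionotropic glutamate receptors were higher for 9 of 16 and lower for 2 (median 0.54, adjusted p 0.0419), with the AMPA receptor gene GRIA2 at 2.46 (SE 0.06, adjusted p 1.77e-09). Reactive astrocyte genes were lower for 11 of 12 (median -2.38, adjusted p 5.62e-05), with the intermediate filament gene VIM at -3.43 (SE 0.08, adjusted p 8.6e-10). Immediate early genes were lower for 14 of 17 (median -1.24, adjusted p 4.74e-05), with FOS, which neuronal activity and stress induce, at -2.86 (SE 0.05, adjusted p 3.22e-10). HOX genes were lower for 14 of 23, or 15 adjusted over the list alone, and higher for 4 (median -0.74, adjusted p 0.0213), with HOXB8 at -2.02 (SE 0.08, adjusted p 2.5e-08) and HOXB9 at -3.25 (SE 0.14, adjusted p 4.48e-08). The other counts of this paragraph were equal adjusted over the list alone. Each of these 5 lists had adjusted p = 0.697 with an estimated correlation. NTRK2, the receptor for BDNF, was lower at -2.74 (SE 0.07, adjusted p 1.62e-09), within a growth factor list that did not pass (median 0.17, adjusted p 0.875, placed lower by camera). The retinoic acid and amyotrophic lateral sclerosis lists had medians of 0.07 and 0.13 while camera placed them lower, without a call (adjusted p 0.875 for both).

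**Figure D4:**
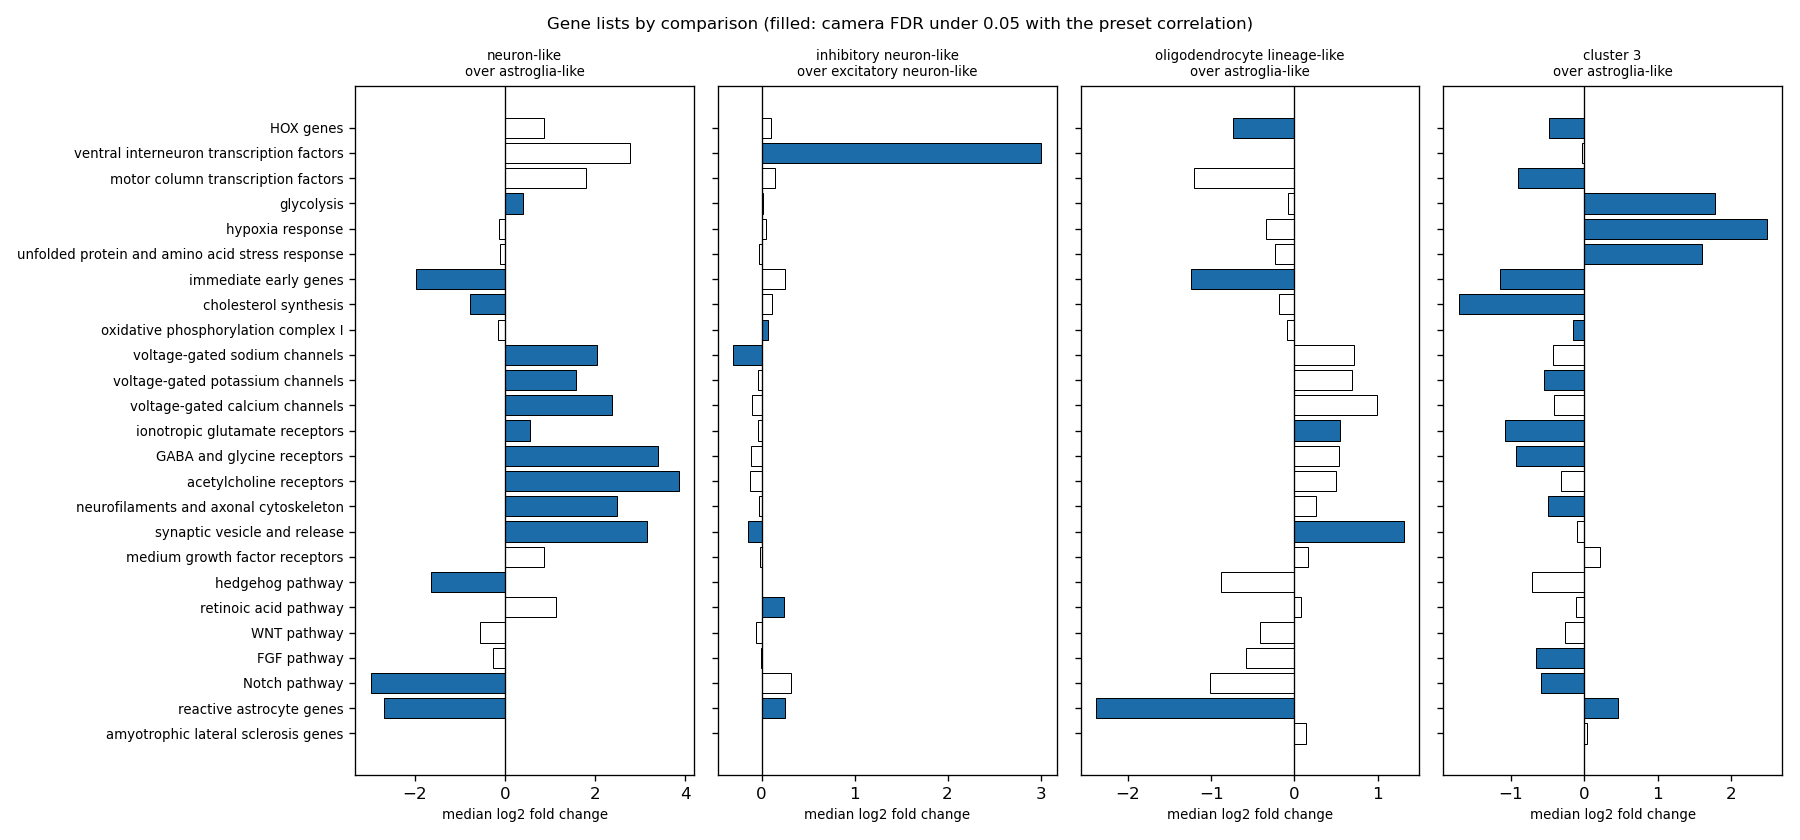
Median log2 fold change of each gene list in 4 comparisons between cell classes, with filled bars for lists with a camera adjusted p under 0.05 at the preset correlation. Synaptic vesicle genes reach 3.14 in neuron-like over astroglia-like cells, and ventral interneuron factors 3.01 in inhibitory over excitatory cells.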

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

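The alternatives with subtraction of free RNA from barcodes of 200 to 450 UMIs and without unnamed clusters, and the comparison of cluster 3, were chosen after seeing the data. Where values below differ from the reported ones, the cause was not tested. Genes called between inhibitory and excitatory cells went from 290 to 99 with the DESeq2 Wald test and to 154 to 317 with 1 slice left out (154 without slice B). In the oligodendrocyte lineage they went from 5496 to 3529 with a mitochondrial limit of 5%. Astroglia-like cells went from 32.6% to 27.4% with that limit, 27.5% with a minimum of 1000 UMIs and 23.0% at Leiden resolution 1.5. Oligodendrocyte lineage-like cells went from 14.4% to 13.4% without doublet removal, 15.6% at resolution 0.6, 21.8% at resolution 1.5, 16.9% with variable genes of odd and even Ensembl number and 17.2% with genes centred by slice. Ependymal-like cells went from 13.3% to 3.99% with the mitochondrial limit of 5%, 7.27% with 1000 UMIs and 17.0% at resolution 0.6. Floor plate-like cells went from 3.64% to 8.08% with that limit, and no cluster had that name with 1000 UMIs or at resolution 0.6. Neural progenitor-like cells went from 3.59% to 1.78% with that limit and 6.01% with variable genes of odd and even Ensembl number. Unnamed cells went from 17.1% to 28.4% with that limit and 32.7% with 1000 UMIs. Neural crest or Schwann-like cells went from 0.125% to 0.604% without doublet removal, 0.528% with a mitochondrial limit of 20% and 0.558% with genes centred by slice, and slice B then had the most (1.40%, 1.21% and 1.29%). Of neuron-like cells, the unnamed share went from 29.7% to 46.6% with the limit of 5%, 53.0% with 1000 UMIs and 41.4% at resolution 1.5. The inhibitory share went from 19.9% to 7.82% with that limit, 9.61% with 1000 UMIs and 10.8% at resolution 1.5. The excitatory share went from 13.0% to 6.05% and 8.23% with the limit and the minimum. The motor share went from 1.80% to 0.873% with the limit and 2.93% with variable genes of odd and even Ensembl number. The number of lists passing went from 14, 6, 5 and 15 to 0 in all 4 comparisons with an estimated correlation. Between inhibitory and excitatory cells it was 2 to 6 with 1 slice left out (2 without slice B). Transmitter and domain genes at 1% went from 20 to 11 when 2 UMIs were asked for.

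Some named genes turned in sign. In neurons over astroglia 4 of the 89 called did, in 1 alternative. In inhibitory over excitatory cells at resolution 1.5, NEFL came to -0.0302, NEFM to -0.33 and NR2F1 to -0.65. In the oligodendrocyte lineage with a mitochondrial limit of 5%, ALDOA came to 0.0665, PKM to 0.0460, ADM to 0.47, ATF3 to 0.39, TUBA4A to 0.0673 and HOXA7 to -0.12. There ADM came to 0.11 with variable genes of odd and even Ensembl number and 0.0125 at resolution 1.5, where HOXA6 came to 0.29 and EN1 to 0.30. The cause was not tested. Of the named genes called, 21 of 43 kept the call in every alternative between inhibitory and excitatory cells, 62 of 73 in the oligodendrocyte lineage, 78 of 89 in neurons and 62 of 63 in cluster 3. Inhibitory against excitatory cells could not be run with a mitochondrial limit of 5%, and the motor neuron comparison in no case. Cluster 3 against astroglia-like cells was not run with another clustering, mitochondrial limit or doublet setting. Its 62 of 63 therefore covers fewer alternatives.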

Other observations

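The tests of the hypoxia list of cluster 3 against empty droplets and of motor neurons in other sub-clusters were set before their results were seen, and the other tests below were chosen after seeing the result.

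Cluster 3, compared with astroglia-like cells after the clusters had been seen, carried genes known to respond to low oxygen. It was chosen because ADM, SLC2A1 and HILPDA led it, so the higher hypoxia response (median 2.48) restates that choice and is no test of it. HILPDA (ENSG00000135245, GRCh38 chromosome 7, 128455849 to 128458418), a lipid droplet protein, stood at 792 CPM ± 177 against 52.5 ± 11.6 (SD, n = 3). The first glycolytic enzyme HK2 was at a log2 fold change of 4.25 (SE 0.08, adjusted p 9.69e-13). Glycolysis was higher for 14 of 17 genes and lower for 2 (median 1.78, camera adjusted p 5.85e-07). All 22 cholesterol synthesis genes were lower (median -1.71, adjusted p 5.92e-15), with HMGCS1 at 109 CPM ± 12.8 against 1037 ± 145 (SD, n = 3). Both lists had adjusted p = 0.296 with an estimated correlation. Of 7961 genes tested with edgeR, 2374 were higher and 2374 lower at a Benjamini-Hochberg adjusted p under 0.05.

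Other clusters shared part of this. The floor plate-like cells, 1 cluster with HILPDA among its leading genes, had summed hypoxia genes at 5026 CPM ± 708 and summed glycolysis genes at 11510 ± 1099, against 4959 ± 340 for glycolysis in astroglia-like cells (SD, n = 3). Cluster 13, with 865 cells led by IGFBP2, NRN1 and ETS2, had summed hypoxia genes at 6638 CPM ± 704, against 7508 ± 377 in cluster 3 and 1525 ± 47.0 in astroglia-like cells (SD, n = 3). Cluster 11, with 1011 cells led by CRYAB and GDF15, had the highest summed stress response of these, 8174 CPM ± 510, against 6868 ± 442 in cluster 3 and 2103 ± 22.8 in astroglia-like cells (SD, n = 3).

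Cluster 3 could be a response to low oxygen inside the slices. Its median mitochondrial share was lower than that of astroglia-like cells in each slice, by at least 3.18 percentage points (-3.18). The kept cells of cluster 3 thus lacked the raised share of cells that leaked cytoplasm. Cells above the mitochondrial limit had been removed before clustering, so the share cannot decide whether such cells belonged to this state. Damage of other kinds was not tested. The immediate early genes had a median of -1.15 against astroglia-like cells (camera adjusted p 0.00149, and adjusted p = 0.307 with an estimated correlation). Summed, they stood at 1148 CPM ± 262 in cluster 3 and 3010 ± 920 in astroglia-like cells (SD, n = 3). In cluster 14, of the oligodendrocyte lineage, they stood at 312 ± 52.5 (SD, n = 3). Classes differed widely in these genes, so the median does not decide on a response to dissociation. The summed hypoxia genes were at least 2.89 times those of empty droplets. That list holds ADM, SLC2A1 and HILPDA, for which the cluster was chosen, so the choice favoured a high ratio. The amino acid stress genes had a median of 2.54, so low oxygen and a shortage of nutrients could not be told apart.

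Motor neuron-like cells were few, 1.80% of neuron-like cells, and 2.93% with variable genes of odd and even Ensembl number. With a minimum of 1000 UMIs the share was 0.773 of the reported one (1.39%), and with a mitochondrial limit of 20% it was 0.940 of it (1.69%). Unnamed neurons rose to 53.0% and 35.3% there, so these shares do not show whether the filters removed motor neurons. Neurons with UMIs of ISL1 or MNX1 together with SLC18A3, SLC5A7 or CHAT were also counted. Without the sub-clusters set aside, 12 such neurons lay outside the motor neuron-like sub-cluster, against 41 inside it. These genes are among the markers that named that sub-cluster, so the count does not decide whether motor neurons lay elsewhere. Its cells also had more UMIs, a median of 15320 against 6803 in inhibitory and 7355 in excitatory neuron-like cells. Loss of motor neurons during dissociation may add to their small number and was not tested.

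With 3 slices the 6 sums of a comparison can be parted in 10 ways, too few for a p value under 0.05. In each of the 4 comparisons 1 of 10 splits, the real one, called as many genes as reported (5763, 290, 5496 and 4748), and the highest other number was 0. Every other split puts sums of both classes on each side, so the class difference enters the residual spread. The 0 calls there therefore say nothing about chance.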
